A study of Mus musculus with 14 samples.

How the data were processed

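The data are 3' end mRNA sequencing of 14 kidney samples of female C57BL/6J mice, 8 under control treatment and 6 under empagliflozin. Per the labels' protocols, RNA was isolated with a NucleoSpin RNA kit and libraries were made with the Lexogen QuantSeq 3' mRNA kit, which reads the end of each transcript, so that counts do not grow with transcript length. Per the submitters' processing notes, cutadapt, STAR and featureCounts were used; versions and settings are not given in the sources used here. The notes name the builds GRCm38 and GRCh38 without a role for either. All gene identifiers in the table are mouse identifiers, and GRCm38 was taken as the build. Whether molecular identifiers were used to count molecules is not given in the sources used here, so counts are treated as reads, which are not independent molecules, and errors from counting are lower limits. How strand was used in counting is also not given, so reads of overlapping or antisense genes cannot be told apart.

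The deposited table holds raw counts per gene, whole numbers that the authors did not normalise, for 54532 genes, of which 21018 had a count in at least 1 library. Gene names and coordinates came from GENCODE M21 on GRCm38, which matched 54409 identifiers and left 123 unmatched. Each column was assigned to its sample by name, and its group was taken from the labels. Sample numbers run from 1 to 9 without 3 in the control group and from 10 to 15 in the empagliflozin group. Total counts per library ranged from 6150931 to 10190213. No 2 libraries agreed within sampling noise: over the 91 pairs, the chi-square statistic per degree of freedom ranged from 14.4 to 66.9. Y-linked genes had no counts and Xist was detected in all libraries of these female mice.

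Differential expression was computed from the counts with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by edgeR's filter on expression by group, which left 12721. Libraries were scaled by TMM factors, and the quasi-likelihood F test with robust estimation compared the groups, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 48.8%. Log2 fold changes are empagliflozin over control, and their standard errors were derived from the F statistic. Fold intervals are 95% intervals with 12 residual degrees of freedom. CPM values are counts per 1e6 counts scaled by TMM, and log2 CPM values carry a prior count of 2. The median log2 fold change over all genes was 0.0096.

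Gene lists for nephron segments, leukocytes, complement, infection, metabolism and stress were fixed before the data were examined, as were the tests, apart from those named below as added. Of 40 lists, 37 had at least 3 tested genes; those of T cells, cytotoxic lymphocytes and adipose or adrenal tissue had fewer and were not tested. Lists were tested with camera on voom values with a preset correlation of 0.01, again with an estimated correlation, with fry, and by an exact permutation test of each list mean. Single values were compared with exact two-sided permutation tests over all 3003 splits of the samples into groups of 8 and 6, and pooled correlations with 100000 permutations.

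Genes named in the text follow a rule fixed before the data were examined. They are the 5 genes with the smallest p in each direction, since fewer than 5 passed, leaving out predicted genes; C1qa, C1qb, C1qc, Slc5a2 and Slc5a1; up to 4 members with the smallest p of each list described; and genes that an alternative or a far value singles out. Cpt1a, S100a8, S100a9, Il1b, C3 and the mitochondrial genes of the closing section fall outside the rule and were chosen after their values were seen.

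The expected count of a gene in a library was its mean share of the counts in the other 13 libraries times the library's scaled total. The share of genes at 0 among those expected at 20 to 40 counts then measures how often reads of a gene are missing altogether.

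The procedure was tested on simulated negative binomial counts with the means, dispersions and library sizes of these data and 200 changed genes of at least 5 CPM. For this comparison it recovered 2.0% of genes changed 1.5-fold (12262 genes tested), 48.5% of those changed 2-fold (12246 genes tested) and 87.5% of those changed 4-fold (12246 genes tested). It thus missed many 2-fold changes, and the absence of a call does not show that a gene was equal between the groups.

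Alternatives covered other scaling factors, no filter and a stricter filter (CPM of at least 5 in at least 6 samples), tests with DESeq2 1.42.0 and limma voom with sample weights, a surrogate variable from sva 3.50.0, and each library left out in turn. The number of genes detected as a covariate, the exclusion of the 3 libraries with most undetected genes and the permutation test of list means were added after seeing the data. The labels give no batch, and no replicate number is shared between the groups, so samples were not paired.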

Results

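Gene expression was measured in whole kidneys of female C57BL/6J mice with an experimental urinary tract infection. Empagliflozin inhibits SGLT2, the sodium-glucose cotransporter of the proximal tubule. Mice received 20 mg/L of the drug or control treatment for 3 days, and uropathogenic E. coli strain 536 was then instilled into the bladder 2 times, 3 hours apart. Kidneys were taken 16 hours after the second instillation. Sequencing of mRNA 3' ends gave 8 control and 6 empagliflozin libraries. Every sample was infected, so the data hold one comparison, that of empagliflozin with control treatment in the infected kidney. Total counts ranged from 6150931 to 10190213 per library. The labels do not state that each library came from a different mouse, so the p-values measure the spread between these samples.

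The libraries of the empagliflozin group held fewer detected genes. A count of at least 1 was found for 14036 ± 633 genes (SD, n = 6), against 15105 ± 614 in the control group (SD, n = 8; exact permutation p = 0.0113, adjusted p = 0.0566 over 5 library measures). Among genes whose expected count lay between 20 and 40, 8.99% ± 5.48 (SD, n = 6) had no count at all in the empagliflozin libraries and 3.29% ± 4.21 (SD, n = 8) in the control libraries (exact permutation p = 0.04995). The largest such shares were 15.6% in empagliflozin 11, 14.5% in empagliflozin 14, 10.7% in empagliflozin 12 and 10.5% in control 8. Mitochondrial genes took 20.6% ± 3.82 of the counts under empagliflozin (SD, n = 6) and 20.1% ± 1.52 under control treatment (SD, n = 8; exact permutation p = 0.743). Hemoglobin genes took 0.103% ± 0.126 and 0.0522% ± 0.0353 of the counts (SD, n = 6 and n = 8; exact permutation p = 0.349), a difference of 0.0506 points that was 0.00518 without empagliflozin 15, and total counts did not differ past the threshold (exact permutation p = 0.135).

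**Figure D1:**
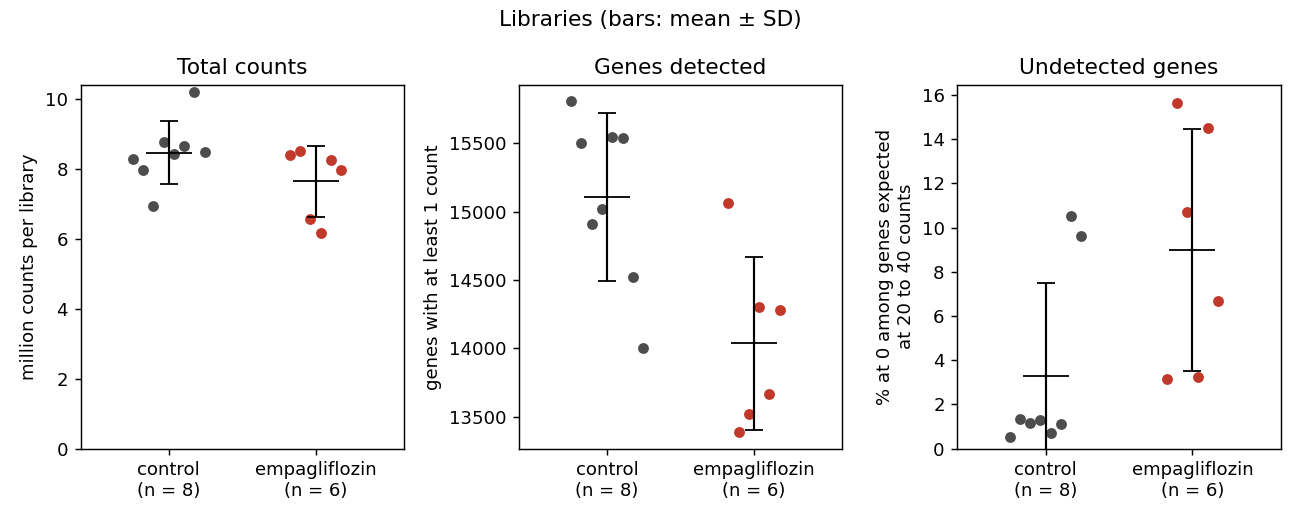
Total counts, genes with at least 1 count, and the percentage of genes at 0 among those expected at 20 to 40 counts, for each of the 8 control and 6 empagliflozin libraries (points), with the group mean and SD (bars). The number of genes detected was 15105 in the control group and 14036 in the empagliflozin group, on an axis that does not start at 0.

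The first question was which transcripts differed between treated and untreated infected kidneys. The leading genes with higher values under empagliflozin included Mal, which encodes an apical membrane protein of tubule epithelium, and Lars2, the mitochondrial leucyl-tRNA synthetase. Those with lower values included Cd63, a tetraspanin of late endosomes and lysosomes, Sdhaf4, an assembly factor of succinate dehydrogenase, and Cyp4a14, a fatty acid omega-hydroxylase. None of the 12721 genes tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and the smallest adjusted p was 0.134. At an unadjusted p under 0.05 there were 921 genes, 426 with higher and 495 with lower values under empagliflozin. DESeq2 called 27 genes (8 higher, 19 lower), of which 18 were among the 12721 genes tested in edgeR and 9 were not. It had 1333 genes at an unadjusted p under 0.05. Limma voom with sample weights called 0, with 1186 at an unadjusted p under 0.05. Of the 10 leading genes named here, 9 were among the DESeq2 calls, as were Tyrobp and Fos, described below.

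Mal (ENSMUSG00000027375, chromosome 2, 127633226 to 127656695) measured 404 ± 47.1 CPM in controls (SD, n = 8) and 613 ± 91.0 under empagliflozin (SD, n = 6), a log2 fold change of 0.60 with SE 0.12 and an edgeR adjusted p of 0.134. Cd63 (ENSMUSG00000025351, chromosome 10, 128900989 to 128912822) measured 1861 ± 554 CPM in controls (SD, n = 8) and 1054 ± 141 under empagliflozin (SD, n = 6), a log2 fold change of -0.82 with SE 0.16 and an edgeR adjusted p of 0.134. All 6 empagliflozin samples lay above the control median for Mal and below it for Cd63. Over the alternatives Mal ranged from 0.46 to 0.66 and Cd63 from -0.90 to -0.45. The other leading genes with higher values were Dhx32, a DEAH-box helicase (log2 fold change 1.27, SE 0.30), Lars2 (0.76, SE 0.19), Tmem30b, a subunit of phospholipid flippases (1.12, SE 0.28), and the secreted ligand Wnt10a (4.05, SE 0.95). Wnt10a was scarce, at 0.345 CPM in controls and 5.96 CPM under empagliflozin, with 3 libraries at 0. Lower values were found for Sdhaf4 (-1.15, SE 0.23), Ptcd2, a mitochondrial RNA-binding protein (-0.78, SE 0.17), Cyp4a14 (-0.75, SE 0.16) and the antitrypsin gene Serpina1d (-0.99, SE 0.21). Their edgeR adjusted p-values lay between 0.144 and 0.255, with all 6 empagliflozin samples on the same side of the control median for each. Serpina1d and Cyp4a14 belong to families of similar paralogs, whose reads the counting may have split, so their values are uncertain.

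The title of the series names complement C1q, and its chains C1qa, C1qb and C1qc were therefore examined as a list of their own. They encode the recognition subunit of the classical complement pathway, made in the kidney mainly by macrophages, and lie side by side on chromosome 4 (GRCm38, C1qa at 136895917 to 136898803, C1qc at 136889804 to 136893065 and C1qb at 136880129 to 136886187, all on the minus strand). The mean log2 CPM of the 3 chains was 4.22 ± 0.39 in controls (SD, n = 8) and 3.24 ± 0.73 under empagliflozin (SD, n = 6). The difference of -0.98 (SE 0.33) passed the exact two-sided permutation test (p = 0.00799), and 4 of the 6 empagliflozin samples lay below the lowest control. The mean log2 fold change of the 3 chains in the fit was -0.71. As 1 of 37 lists, the chains did not pass: the camera adjusted p was 0.0961, and the adjusted p was 0.901 with an estimated correlation, 0.287 in limma's directional fry and 0.255 in the exact permutation test of list means. The list passed in camera with control 4, control 7 or empagliflozin 15 left out. The chains did not contribute alike. C1qa measured 20.2 ± 5.19 CPM in controls (SD, n = 8) and 11.9 ± 4.52 under empagliflozin (SD, n = 6), a log2 fold change of -0.77 with SE 0.29. C1qc measured 10.9 ± 4.27 and 4.87 ± 4.65 CPM (SD, n = 8 and n = 6), a log2 fold change of -1.16 with SE 0.59, with 1 empagliflozin library at 0. C1qb, the most abundant chain, measured 33.6 ± 14.4 and 29.3 ± 10.99 CPM (SD, n = 8 and n = 6), a log2 fold change of -0.19 with SE 0.28 whose fold interval, 0.569 to 1.34, spans both directions. When the CPM of the 3 chains were summed, the difference was -18.6 CPM (64.7 against 46.0, exact permutation p = 0.0763).

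Of the 3 chains, 0 passed over all genes (C1qa adjusted p = 0.521 in edgeR's quasi-likelihood test) and 1, C1qa, passed adjusted over the list alone (adjusted p = 0.0367). The series title names C1q, and whether that choice came from these samples is not given in the sources used here. Neither this count nor the permutation p of the mean, unadjusted for that choice, can thus be taken as independent evidence of the C1q direction. Without empagliflozin 11, 12 and 14, the 3 libraries with most undetected genes, the difference in the mean was -0.56 (exact permutation p = 0.145), and no chain passed over the list alone. C1qa also missed that threshold when control 1, 2, 5 or 9 or empagliflozin 13 was left out, or empagliflozin 12 or 14 singly, and 2 chains passed it without empagliflozin 15.

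**Figure D2:**
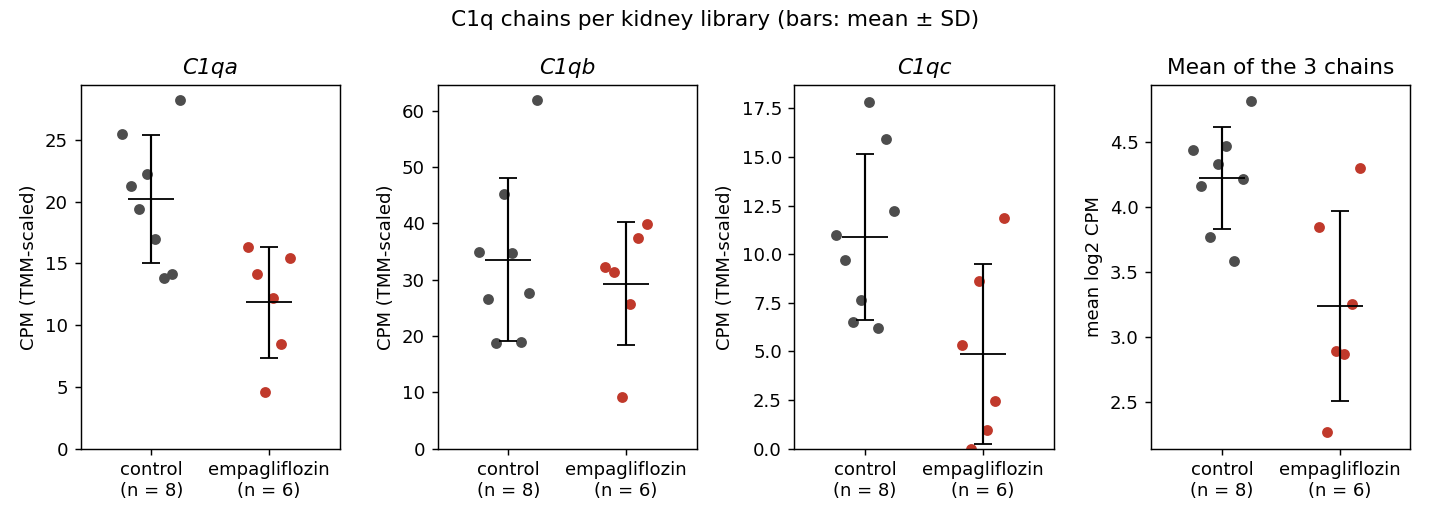
CPM of C1qa, C1qb and C1qc and the mean log2 CPM of the 3 chains in each of the 8 control and 6 empagliflozin libraries (points), with the group mean and SD (bars). The mean of the chains was 4.22 in controls and 3.24 under empagliflozin, while C1qb overlapped between the groups.

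Other macrophage transcripts were set beside C1q to ask whether it differed from them. The mean of 13 macrophage markers was 2.77 ± 0.30 log2 CPM in controls (SD, n = 8) and 2.41 ± 0.41 under empagliflozin (SD, n = 6), a difference of -0.36 (exact permutation p = 0.0803), while their mean log2 fold change in the fit was -0.16. Random lists matched to them on expression had a median difference of -0.18. Of these markers 5 had higher and 8 lower values, and 0 passed over all genes or adjusted over the list alone. Mertk, a receptor for the uptake of dying cells, had a log2 fold change of -0.61 (SE 0.23), Aif1 one of -1.01 (SE 0.62), and Csf1r, the receptor that macrophages need to survive, one of -0.33 (SE 0.21). C1q minus the macrophage mean differed by -0.62 between the groups (SE 0.27, exact permutation p = 0.0393). That difference missed the threshold with the monocyte list as the reference (-0.65, exact permutation p = 0.148) and without the 3 libraries named above (-0.33, exact permutation p = 0.339). With single libraries left out it ranged from -0.78 to -0.49 and passed only without control 1, control 7, empagliflozin 10 or empagliflozin 15.

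Across the 14 samples, the C1q mean and the macrophage mean had a Pearson r of 0.652 (permutation p = 0.0124, adjusted p = 0.112 over 9 relations) and a Spearman rho of 0.640 (permutation p = 0.0164, adjusted p = 0.148). Without the 2 samples farthest from the median macrophage level, r was 0.418 (permutation p = 0.175). Within the control group r was 0.186 (n = 8, rho 0.0714, exact permutation p = 0.658 and 0.882) and within the empagliflozin group 0.687 (n = 6, rho 0.486, exact permutation p = 0.129 and 0.356). With monocyte markers the pooled r was 0.350 (rho 0.0505, permutation p = 0.223 and 0.869), and with neutrophil markers 0.290 (rho 0.191, permutation p = 0.312 and 0.513). None of the 9 relations passed after adjustment. The spread of the neutrophil, cytokine and macrophage means between samples was 1.203, 1.54 and 1.35 times as large under empagliflozin as in controls, with exact permutation p-values of 0.491, 0.301 and 0.523. With the median over the list in place of the mean, the neutrophil ratio was 2.03 (exact permutation p = 0.154).

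The drug's target and the transporters around it came next. Slc5a2, which encodes SGLT2, measured 275 ± 81.2 CPM in controls (SD, n = 8) and 255 ± 49.3 under empagliflozin (SD, n = 6), a log2 fold change of -0.11 with SE 0.16 and a fold interval of 0.729 to 1.18. Slc5a1, which encodes SGLT1 of the late proximal tubule, had a log2 fold change of -0.18 (SE 0.25). Of the 15 glucose and sodium transport genes, 4 had higher and 11 lower values; 0 passed over all genes and 2 passed adjusted over the list alone, among them Slc9a3, and the list as a whole did not pass (camera adjusted p = 0.758). Slc9a3, the sodium-proton exchanger NHE3, rose by that count from 34.0 ± 7.29 CPM (SD, n = 8) to 57.3 ± 18.7 (SD, n = 6), a log2 fold change of 0.75 with SE 0.20 and a list-adjusted edgeR p of 0.0101.

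Among 22 tested genes of fatty acid oxidation and ketone body synthesis, 14 had lower and 8 higher values. None passed over all genes, and 4 fell by the count adjusted over the list alone. Among them were Cyp4a14, its neighbour and paralog Cyp4a10 (log2 fold change -0.48, SE 0.15) and Hadha, a subunit of the mitochondrial trifunctional protein (-0.40, SE 0.13). All 6 empagliflozin samples lay below the control median for each of these 3 genes. Cpt1a, which admits fatty acids to mitochondria, went the other way (0.23, SE 0.13) without passing. The list did not pass as a whole against other genes in camera (adjusted p = 0.395). In limma's fry, the mixed test, which asks for change in either direction, gave this list an adjusted p of 0.0371 over 37 lists, the smallest of them. Gluconeogenesis (difference of list means -0.09, camera adjusted p = 0.892), glycolysis (-0.22, camera adjusted p = 0.994), nuclear genes of oxidative phosphorylation (-0.03, camera adjusted p = 0.981) and mitochondrially encoded genes (0.06, camera adjusted p = 0.905) did not pass.

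Along the nephron, genes of the collecting duct's principal cells had higher values. These cells take up water and sodium under vasopressin and aldosterone. All 9 markers were higher, with a mean log2 fold change of 0.49. Fxyd4, a regulator of ion transport, had a log2 fold change of 0.94 (SE 0.31), the water channel gene Aqp3 one of 0.50 (SE 0.20), the sodium channel subunit gene Scnn1g one of 0.68 (SE 0.31) and the vasopressin receptor gene Avpr2 one of 0.58 (SE 0.29). Without empagliflozin 12, Fxyd4 was at 0.50 and Avpr2 at 0.36. Over all alternatives Fxyd4 ranged from 0.16 to 1.09 and Avpr2 from 0.06 to 0.69, while Aqp3 stayed between 0.44 and 0.61 and Scnn1g between 0.57 and 0.98. None of the 9 passed over all genes or adjusted over the list alone. The list rose in camera with its preset correlation (adjusted p = 6.5e-05), but not with an estimated correlation (adjusted p = 0.312), in directional fry (adjusted p = 0.287) or in the exact permutation test of the list mean (p = 0.0206, adjusted p = 0.255). Without empagliflozin 11, 12 and 14 its mean log2 fold change was 0.21 (camera adjusted p = 0.362).

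Of 10 intercalated cell markers 8 were higher, among them the anion exchanger Slc4a1 (0.90, SE 0.36) and the proton pump subunit Atp6v0d2 (0.45, SE 0.23), and the list missed the threshold (camera adjusted p = 0.0650, and 0.901 as the adjusted p with an estimated correlation). It passed in camera with control 1, 2, 4 or 5 or empagliflozin 14 or 15 left out. Thick limb markers differed by 0.10 in their mean (camera adjusted p = 0.187), with Umod at 0.21 (SE 0.12), and distal convoluted tubule markers by -0.12 (camera adjusted p = 0.756). The means of 18 proximal tubule markers were 8.59 ± 0.14 log2 CPM in controls (SD, n = 8) and 8.60 ± 0.15 under empagliflozin (SD, n = 6; camera adjusted p = 0.756). Podocyte (0.08, camera adjusted p = 0.742), endothelial (0.06, camera adjusted p = 0.515), urothelial (0.05, camera adjusted p = 0.905) and erythroid (0.15, camera adjusted p = 0.394) list means did not differ past the threshold either. The thick limb list passed in camera without control 4, and the erythroid list without control 5 or empagliflozin 10.

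**Figure D3:**
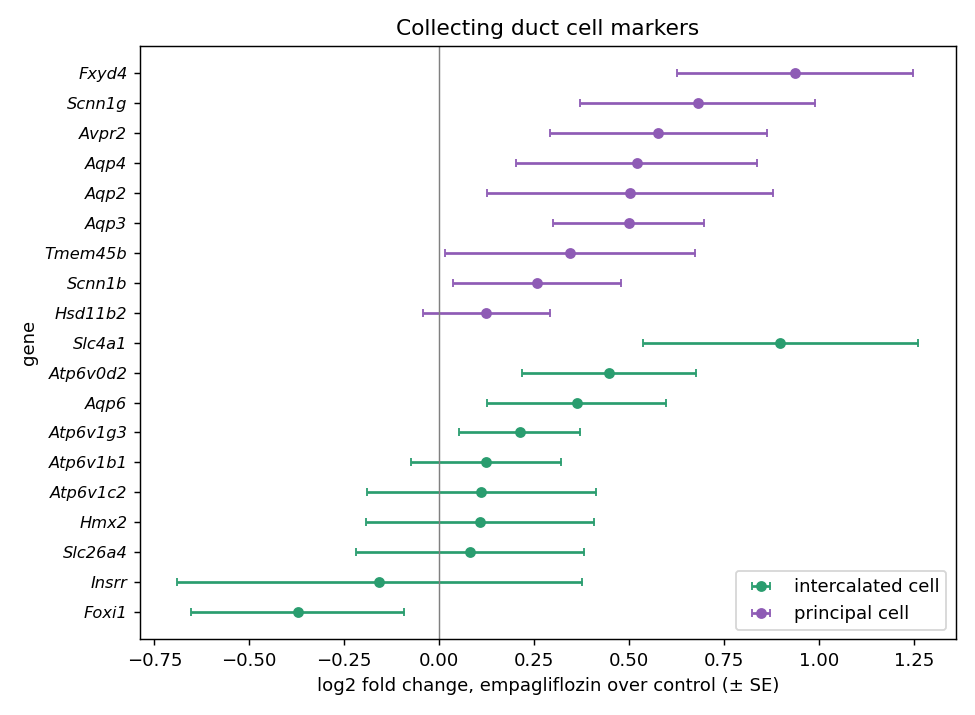
Log2 fold change of each tested principal cell and intercalated cell marker, empagliflozin over control (points), with its standard error (bars), from 8 control and 6 empagliflozin libraries. All 9 principal cell markers lie above 0, as do 8 of the 10 intercalated cell markers.

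No list of infection response genes passed the threshold in camera with all 14 libraries and treatment as the only term, and the errors were wide. The neutrophil list passed in camera with the number of genes detected as a covariate. The interferon list passed in camera without control 2 and the antimicrobial list without empagliflozin 10. Neutrophil markers had a mean difference of -0.71 (SE 0.48), with 7 of 9 lower and a camera adjusted p of 0.256, including the neutrophil protease inhibitor gene Wfdc21 (-2.49, SE 1.12) and the lectin receptor gene Clec4e (-1.42, SE 0.84), and S100a8 and S100a9, the abundant calprotectin genes, had log2 fold changes of 0.01 (SE 0.48) and -0.06 (SE 0.52). Of 12 antimicrobial genes 10 were higher (camera adjusted p = 0.237), including Lcn2, which withholds iron from bacteria, at 0.76 (SE 0.70), and Slpi at 0.85 (SE 0.59). Of 13 cytokine and NF-kB genes 10 were higher (camera adjusted p = 0.758), with Ccl4 at 0.57 (SE 0.58), Il1b at -0.17 (SE 0.45) and Nfkbia at 0.30 (SE 0.19). Genes of antigen presentation and dendritic cells were lower in 8 of 9 cases, among them H2-DMb1 (-0.91, SE 0.33) and Batf3 (-2.78, SE 1.30, with 7 libraries at 0), and the list missed the threshold (camera adjusted p = 0.211). List means differed by 0.15 for interferon-induced genes (camera adjusted p = 0.394), -0.28 for receptors of bacterial products (mean log2 fold change -0.08, camera adjusted p = 0.491), -0.34 for monocyte markers (camera adjusted p = 0.758, with a mean log2 fold change of 0.11 and 5 of 7 genes higher) and -0.52 for B and plasma cell markers (mean log2 fold change -0.16, camera adjusted p = 0.681). None of the genes in these lists passed over all genes or adjusted over its list alone.

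The lists of complement genes other than C1q did not pass in camera, and neither did that of the C1q chains. The mean of 10 further components differed by -0.29 (mean log2 fold change -0.09, camera adjusted p = 0.787), with C3 at -0.32 (SE 0.50) and Cfb of the alternative pathway at 0.41 (SE 0.41), and that of 12 regulators and receptors by -0.15 (camera adjusted p = 0.892), although its mean log2 fold change was 0.05. Of 14 genes of the phagocyte oxidase and Fc receptor signalling, 1 fell by the count adjusted over the list alone: Tyrobp, the signalling adaptor of myeloid receptors, measured 9.40 ± 2.27 CPM in controls (SD, n = 8) and 3.30 ± 1.48 under empagliflozin (SD, n = 6), a log2 fold change of -1.51 with SE 0.41 and a list-adjusted edgeR p of 0.0128. Cybb, the catalytic subunit of the oxidase, was higher without passing (0.77, SE 0.28), and the list did not pass (camera adjusted p = 0.994).

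Immediate-early and heat shock genes, which respond within minutes to stimulation or handling of tissue, were higher in 10 of 12 cases. Fos rose by the count adjusted over the list alone, from 1.45 ± 1.06 CPM (SD, n = 8) to 8.03 ± 6.94 (SD, n = 6), a log2 fold change of 2.46 with SE 0.64 and a list-adjusted edgeR p of 0.00812. Egr1 had a log2 fold change of 0.80 (SE 0.32). The list rose in camera with its preset correlation (adjusted p = 0.0298), but not with an estimated correlation (adjusted p = 0.901). Without empagliflozin 12 its mean log2 fold change was 0.35 instead of 0.60 (camera adjusted p = 0.359), and it also missed the threshold without control 1, 6, 8 or 9 or empagliflozin 13. Tubule injury genes differed by -0.14 in their mean (camera adjusted p = 0.756), although 11 of 19 were higher and the mean log2 fold change was 0.01, with the keratin gene Krt18 at 1.28 (SE 0.46). Hypoxia (0.05, camera adjusted p = 0.722), Nrf2 (-0.15, camera adjusted p = 0.932), endoplasmic reticulum stress (0.05, camera adjusted p = 0.758), clock (-0.04, with a mean log2 fold change of 0.05, camera adjusted p = 0.949) and sterol synthesis (-0.15, camera adjusted p = 0.758) list means did not pass.

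**Figure D4:**
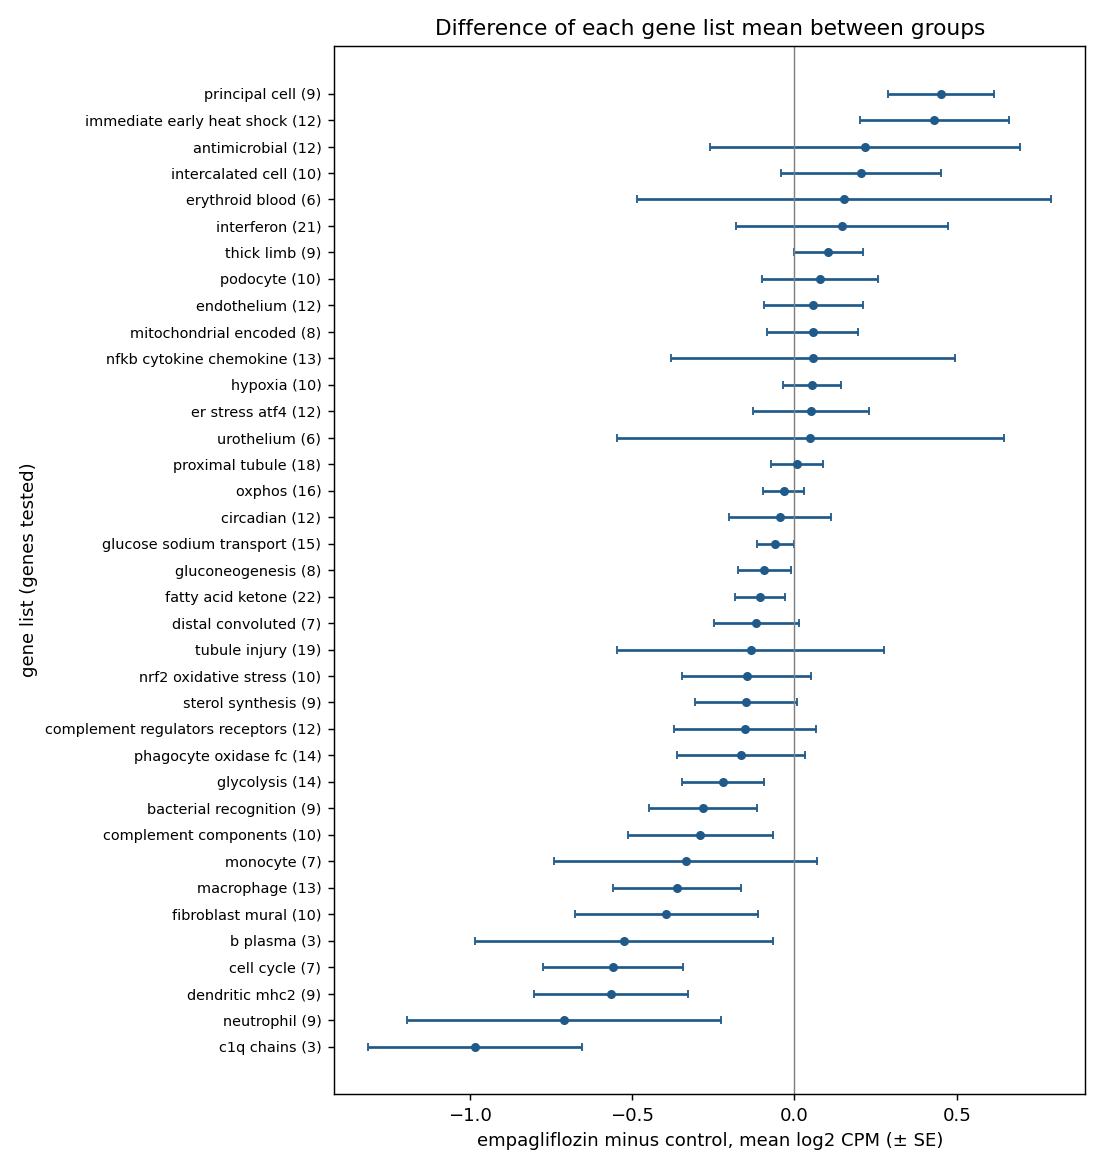
Difference in mean log2 CPM between the 6 empagliflozin and 8 control libraries for each of the 37 gene lists tested (points), with its standard error (bars) and the number of genes in brackets. The principal cell list lies highest at 0.45 and the C1q chains lowest at -0.98.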

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

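Each value here is a sample whose gap to the rest of its group exceeded the 95% limit of Dixon's test for a single far value. Of 174 groups of values tested, 13 exceeded it, where chance gives about 1 in 20, or 8.7. No explanation was tested for these values.

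Control 9 stood apart from the other controls in several lists: its mean was 6.12 log2 CPM for glycolysis (next highest 5.81), 7.39 for oxidative stress genes of the Nrf2 response (next 6.58) and 3.17 for clock genes (next lowest 3.77). Its value for Hif1a, the oxygen-regulated transcription factor, was 6.40 log2 CPM against 5.71 in the next control. Hif1a was higher under empagliflozin with a log2 fold change of 0.63 (SE 0.20), which passed only adjusted over the hypoxia list alone (edgeR list-adjusted p = 0.0381).

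The interferon-induced genes had a mean of 4.73 log2 CPM in control 2, with the other controls between 2.55 and 3.42. The immediate-early and heat shock list had a mean of 4.98 in control 4, with the next control at 4.54. Podocyte markers had a mean of 3.17 in empagliflozin 14, with the other treated samples between 3.94 and 4.34. The endoplasmic reticulum stress list reached 5.55 in empagliflozin 12 against 4.88 in the next sample.

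Among the named genes, C1qb was lowest in empagliflozin 12, at 3.25 log2 CPM, with the other treated samples between 4.70 and 5.33. Tmem30b was 2.52 in control 6, below the next control at 3.66, and 6.12 in empagliflozin 12, above the next treated sample at 5.02. The scarce dendritic cell gene Batf3 was detected in a single treated library, empagliflozin 15, at 1.15 log2 CPM. The neutrophil gene Wfdc21 reached 1.65 in empagliflozin 13, with the next treated sample at -0.996.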

How the results depend on the processing

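The detection covariate, the exclusion of empagliflozin 11, 12 and 14, and the permutation test of list means were chosen after seeing the data; all other alternatives were planned. No paired analysis was possible because the groups share no replicate number. The alternatives were followed for 43 genes, of which 38 kept their direction in each run that held them. Other genes named in the text were not followed, so their directions under the alternatives are not given. At the depth and spread of these libraries the gene-level test recovered 2.0% of simulated 1.5-fold changes; other depths were not simulated.

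The count of genes past the threshold was 0 with other scaling factors, the stricter filter, robust estimation off, sample weights, the detection covariate and without the 3 libraries. It was 12 with no filter (3 higher, 9 lower; 6 of the 10 leading genes), 27 with DESeq2 (17491 genes tested; 9 of the 10 leading genes) and 2 with a surrogate variable (Rps27a and Sema4a). Leaving out single libraries gave 0 to 2: Cd63 and Ptma without control 9, Rps3a2 without empagliflozin 14 and Nop10 without empagliflozin 15. The cause was not tested.

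The C1q mean differed by -1.19 (without empagliflozin 15) to -0.78 (without empagliflozin 11) when 1 library was left out, past the threshold each time, and by -0.56 without the 3 libraries. The number of chains past the threshold over the list alone was 1, and 0 with a surrogate variable, with the detection covariate and without the 3 libraries. It was 0 without control 1, 2, 5 or 9 or empagliflozin 12, 13 or 14, and 2 without empagliflozin 15. C1q minus macrophage markers was -0.65 with the monocyte list, -0.61 with the median (exact permutation p = 0.109), -0.64 with a prior count of 0.5 (exact permutation p = 0.0676) and -0.33 without the 3 libraries, all short of the threshold, and -0.82 with the phagocyte list, past it. Leaving out single libraries gave -0.78 to -0.49, past the threshold only without control 1 or 7 or empagliflozin 10 or 15. The correlation of C1q with macrophage markers was 0.502 after centring each group (permutation p = 0.0663) and 0.418 without 2 samples; that with neutrophil markers turned to -0.0787 without 2 samples.

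The number of lists past the threshold was 2, against 1 with no filter, with the stricter filter and with a surrogate variable, 3 with the detection covariate (neutrophil, principal and intercalated cell lists), and 0 with an estimated correlation, directional fry, permutation or without the 3 libraries. Leaving out single libraries gave 1 (control 6, 8 or 9, empagliflozin 12 or 13) to 5 (control 4, with the C1q list among them), and 4 without control 2 or 5 or empagliflozin 10 or 15. The principal cell mean log2 fold change was 0.49 with an estimated correlation or directional fry, neither past the threshold, and 0.21 without the 3 libraries; it stayed past it with each single library left out (0.36 to 0.58). The immediate-early list missed the threshold at 0.47 with no filter, 0.45 with the stricter filter, 0.44 with a surrogate variable, 0.29 with the detection covariate, 0.34 without the 3 libraries and 0.60 with an estimated correlation or fry; leaving out single libraries gave 0.35 (empagliflozin 12) to 0.69, short of it in 6 cases.

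Slc5a2 ranged from -0.196 to 0.0379 with single libraries left out, turning without control 9. Directions also turned for Slc5a1 (0.0134), Aif1 (0.0522) and Ccl4 (-0.00181) with the detection covariate, and for Slpi without the 3 libraries (-0.41). Without empagliflozin 12, Ccl4 was at 0.17, Slpi at 0.34 and Nfkbia at 0.14; without empagliflozin 15, Aif1 was at -1.77; without control 2, H2-DMb1 was at -0.60; and without control 9, C1qb was at -0.01. The difference in mitochondrial percent was -0.591 without empagliflozin 11, -0.261 without 12 and at most 1.18; that in the share of the top 10 genes ranged from -0.201 (without empagliflozin 11) to 1.24, and the ratio of macrophage spreads from 0.751 (without empagliflozin 15) to 2.02. The neutrophil spread ratio was 2.03 with the median over the list, and the hemoglobin difference ranged from 0.00518 (without empagliflozin 15) to 0.0671. Total counts passed the threshold only without control 4 (-1034790, exact permutation p = 0.0420). The cause was not tested.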

Other observations

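The counts over other splits of the samples for genes and for the number of lists were chosen only after the results were seen, as was the bound for reading C1q minus macrophage markers, itself a comparison set beforehand, as a test of macrophage content; the marker lists of medulla and collecting duct identity were drawn up after the data were examined.

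Stromal, cell cycle, stress and clock genes had higher and lower values. Fibroblast and mural cell markers differed by -0.39 in their mean (camera adjusted p = 0.463), with Acta2, the smooth muscle actin gene, at -1.13 (SE 0.41). In the endothelium 7 markers were higher and 5 lower, among them Emcn (0.47, SE 0.19) and Tek (0.75, SE 0.31) above and Egfl7 (-0.47, SE 0.23) and Esam (-0.33, SE 0.26) below, none past the threshold over the list alone. Cell cycle genes differed by -0.56 (mean log2 fold change -0.27, camera adjusted p = 0.463), with the replication gene Mcm2 at -1.62 (SE 0.60). In the endoplasmic reticulum stress list, Herpud1 fell adjusted over the list alone (-0.42, SE 0.13, edgeR list-adjusted p = 0.0444), with the chaperone gene Hspa5 at -0.37 (SE 0.13), while Sesn2 (0.49, SE 0.23) and Dnajb9 (0.43, SE 0.24) had higher values. Of the clock genes, Dbp rose adjusted over the list alone (0.96, SE 0.29, edgeR list-adjusted p = 0.0346), with Per1 at -0.63 (SE 0.32).

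Fewer genes were detected under empagliflozin. The difference was -1003.6 genes at a common total count (exact permutation p = 0.0123) and -998.1 genes at a common count outside the 10 most abundant genes (exact permutation p = 0.0130), which argues against lower totals and against a few genes taking the counts. Among the 12721 genes tested, genes at 0 were shared between empagliflozin libraries 1.01 times as much as between groups, relative to chance. This argues against wide silencing of particular tested genes. The empagliflozin libraries lacked 332.3 more of the tested genes on average, so most of the difference lies among scarcer genes that the sharing did not cover. Silencing of those, or of a small set, was not decided by it. What also stays open is that fewer distinct molecules may lie behind the counts. The share at 0 among genes expected at 20 to 40 counts was 5.70 points higher (exact permutation p = 0.04995), a p close to the threshold. Whether this came from the tissue or from the handling of the samples was not tested, as the labels give no batch.

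The C1q chains were lower under empagliflozin, and an effect of the drug on their transcription stays open. Their difference of -0.98 lay at percentile 0.0600 of 10000 random triples matched on expression. The series title names C1q, so the triple may have been chosen from these samples. The rank of such a triple cannot decide whether missing molecules alone gave the difference. Related genes also left that range readily, as 8 of the 37 lists lay outside the central 95% of their own random lists. The difference was -0.56 without the 3 libraries with most undetected genes (exact permutation p = 0.145). Lower macrophage content cannot be told apart from lower C1q per macrophage. C1q minus macrophage markers differed by -0.621 (exact permutation p = 0.0393). It stayed between -0.82 and -0.49 with other markers, the median, another prior count or a library left out. These alternatives reuse the same samples, so that range is no separate evidence against macrophage content. The difference was -0.33 without the 3 libraries, and the p often missed the threshold. The bound at first asked only for a p under 0.05 and a difference above 0.5 of that of C1q, which would have counted against macrophage content; asking also for each alternative, after the result was seen, turned this to open.

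The principal cell list was higher. It lay at percentile 100 of 10000 random lists matched on expression (upper bound of the central 95% 0.166, observed 0.452). The random lists were drawn gene by gene, whereas genes of this list varied together, with an estimated correlation of 0.187. Related lists left that range readily, so the rank cannot decide whether missing molecules alone gave the difference. Of 100 splits of the samples, 3, the real one and 2 of the 99 others, gave the list as small a camera adjusted p (6.5e-05, smallest of the others 1.9e-08). The camera adjusted p was 0.312 with an estimated correlation. Without the 3 libraries with most undetected genes the list's mean log2 fold change was 0.21 and missed the threshold in camera, with 3 treated samples left. More medulla or more collecting duct in the tissue cannot be told apart from regulation by the drug. Medullary markers outside the collecting duct differed by 0.169 (SE 0.195, exact permutation p = 0.371). Cortical markers differed by 0.039 (SE 0.130, exact permutation p = 0.757), where more medulla would lower them. Collecting duct identity genes outside the list differed by 0.188 (SE 0.084, unadjusted exact permutation p = 0.0403), with 6 of 7 higher. The medullary and identity values are 0.375 and 0.415 of the list's difference, and the errors leave a share above or below 0.5, and a lower cortex, open.

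The real grouping was set beside 99 other splits of the 14 samples into groups of 8 and 6, which with it make 100. With 0 genes past the threshold in the real grouping (edgeR; 27 in DESeq2 and 0 in voom), all 100 give at least as many whatever the data, so that count says nothing about chance; the highest other gave 1. The 921 genes at an unadjusted p under 0.05 exceeded the 636.05 of uniform p-values and the median of 426 in the other splits, but 5 of the 99 gave at least as many, up to 1229. At least 2 lists passed in 83 of the 100, of which 82 were other splits, with up to 13 lists, so chance cannot be excluded for the number of lists. Genes that vary together within lists could alone give such counts, since camera's preset correlation was 0.01 and estimates reached 0.492; a structure of the samples other than treatment was not tested.

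Mitochondrial counts were spread unevenly over genes: the 14 libraries held 11878567 counts for mt-Nd4 and 225457 for mt-Co1, but 13 for mt-Co2, 4 for mt-Atp6 and 1 for mt-Co3. These genes were chosen after their values were seen.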
